A study of Arabidopsis thaliana with 30 samples.

How the data were processed

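Gene expression was measured on 30 Affymetrix ATH1 arrays hybridised with RNA from sorted Arabidopsis thaliana (Columbia) root cells. Seedlings were 5 days old when they were moved for 24 h to medium of pH 4.6 or pH 5.7, both buffered with 3 mM DMG, and cells came from roots of 6 days. Roots were protoplasted and GFP-positive cells were collected by fluorescence-activated sorting from 5 marker lines. These lines mark the columella, the epidermis with lateral root cap, the cortex, the endodermis with quiescent center, and the stele. Each cell type had 3 replicates at each pH, which gives 10 groups of 3 arrays, and groups and replicate numbers were taken from the sample labels. The labels do not say that replicates came from separate cultures or sorting days, so p-values measure the spread between these samples, which may be technical.

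The deposited values are probe set intensity on a linear scale, which the authors made with MAS5 according to the processing notes, with no version given. The authors' scaling left a trimmed mean of 250.0 on every array. The notes name no genome build, so no coordinates are given. RNA was amplified before hybridisation. The values are intensities and not counts of molecules. The number of arrays limits the precision of each comparison, and the part of RNA input and amplification was not tested.

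Signals were transformed to log2 after adding a pseudocount of 11.9, the percentile 25 of all values. Of 22810 probe sets, 64 Affymetrix controls were set aside. Of the other 22746, those above percentile 40 of their array on at least 3 of the 30 arrays were tested, which left 17038. A table of probe sets and genes gave a single gene for 13513 probe sets and several genes for 503, and 8730 had no gene in it. Of the single-gene probe sets, 13436 matched a gene of the TAIR10.1 annotation, which was used for names alone, and 77 did not. The tested probe sets with a single gene numbered 9514 and covered 9399 genes. Probe sets with no gene or several genes were counted in totals and were never named. Genes without a symbol are named by locus.

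A linear model was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with a mean per group and empirical Bayes moderation with an intensity trend. The fit had 20 residual degrees of freedom, and the prior added 8.32. Contrasts were pH 4.6 minus pH 5.7 in each cell type, their mean over the 5 cell types, and an F test of the differences between the 5 contrasts, called the interaction below. Adjusted p-values are Benjamini-Hochberg values over the 17038 probe sets, with a threshold of 0.05. Folds are 2 to the power of the log2 change and so are smaller than ratios of signals near the pseudocount. Where a mean signal lay under or near the pseudocount, signals are given in place of a fold. Standard errors of log2 changes come from this fit, and ± after a signal is the SD of 3 arrays unless another n is given.

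The model, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. The rule names, in each cell type, the 8 risen and 8 fallen genes with the largest log2 change past the threshold whose 3 and 3 values do not overlap. For the mean response it names the 12 risen and 12 fallen genes with the largest change that go the same way in all 5 cell types. For the interaction it names the 10 genes with the smallest p, and for each list up to 4 members with the largest change past the threshold. It also names 16 genes of proton tolerance and cell identity where they are measured. Of these, AT1G09750 was tested, and the others were not analysed here. The rule gave 114 genes, and the text gives the larger changes among them.

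In all, 32 lists with 551 gene entries were fixed, and 12 lists had at least 3 tested members. List shifts were tested with limma's camera at a preset inter-gene correlation of 0.01, in 72 tests adjusted together, and again with an estimated correlation, beside fry. The 20 lists with fewer tested members have no list test, and the nitrate, phosphate and plasma membrane proton pump lists had 0 tested members. The 34 families, defined by the letters of the gene symbol except for 1 of plastid-encoded genes, were chosen after the data were seen, and the GH3 genes were separated from the GH9 genes only after the members of a first joint family were seen. Ratios of 3 prime to 5 prime control probe sets were compared between pH values by permutation within cell types with 100000 resamples, and by exact permutation tests of 3 against 3 arrays within a cell type. All of these tests were two-sided, and with 3 against 3 the smallest possible p is 0.1.

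Alternatives were a pseudocount of 1 and of 55.3, quantile normalization, equal array medians, no filter and a filter at percentile 60, a replicate block, fits to the 6 arrays of a cell type, robust moderation, array weights, a 2-fold size limit, and leaving out each array. Counts without probe sets at least 4-fold brighter in another cell type were added after seeing the data. The design was tested on simulated data for the columella contrast with 17038 probe sets. Planted changes were recovered for 4%, 54%, 96% and 100% of 50 genes at 0.5, 1, 2 and 3 log2 units, with 7 false calls. A planted list of 10 genes ranked 1, and 2 of 200 null lists had p below 0.05. The simulated noise was independent between probe sets, so it cannot check camera on lists whose members vary together. The estimated correlation was 0.26 for the cortex markers and 0.856 for the wound and touch list. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.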

Results

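The series asked how the main cell types of the Arabidopsis root change their transcripts after 24 h on acidic medium. It holds 30 arrays, 3 for each of 5 sorted cell types at pH 4.6 and at pH 5.7, and pH 5.7 is the control in every comparison. The median signal of an array lay between 43.8 and 71.7. Arrays of a group correlated across probe sets with r between 0.945 and 0.981 (median 0.973). The median r was 0.942 between the pH values of a cell type and 0.797 between cell types, and probe sets are not independent replicates. No array duplicated another.

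Marker genes were compared between cell types first, to see whether the sorted cells carried the transcripts of their labels. AT1G09750, the gene whose promoter drives the cortex reporter, had a signal of 2769 ± 1557 (SD, n = 6) in cortex and 19.0 ± 12.4 to 54.9 ± 28.1 in the other cell types (n = 6 each). The cortex genes AT1G62510 and AT3G21670 (the nitrate transporter NPF6.4) were also highest in cortex, at 2093 ± 940 and 423 ± 53.5 (n = 6). GSO1, a receptor kinase needed for a closed Casparian strip, was highest in endodermis at 5954 ± 1568 (n = 6), with 1146 ± 963 in cortex and 1335 ± 279 in stele. The root hair expansins EXPA7 and EXPA18 were highest in epidermis, at 2197 ± 1814 and 1284 ± 1255 (n = 6), and EXPA7 also reached 993 ± 733 in stele. PHV, a vascular HD-ZIP III gene, was highest in columella (472 ± 80.8) and next in stele (235 ± 110), and AT4G28100 (EN7) and AGL42 were higher in cortex than in endodermis. In all, 7 of the 10 tested markers were highest in the cell type of their list, and the drivers of the epidermis, endodermis and stele lines were not analysed here. LHW, of the stele list, had its highest level in stele at 323 ± 137 but did not differ there from the mean of the other cell types (limma adjusted p = 0.119).

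In columella, the starch-bearing cap cells that sense gravity, low pH gave the largest rises among the named genes of the series. AT2G41730 rose 105-fold, from 82.0 ± 14.4 to 9783 ± 839 (SD, n = 3). AT2G21640, a marker of oxidative stress in mitochondria (UPOX), rose 42.7-fold, from 26.9 ± 8.09 to 1624 ± 81.3. AT3G54520 rose 37.1-fold to 1334 ± 13.3, AT5G42830 rose 34.7-fold to 1249 ± 244, and AT1G05060 rose 28.9-fold from 161.6 ± 14.0 to 4997 ± 267. CHIL, a chalcone isomerase-like protein, was 11.7-fold lower (568.2 ± 30.9 to 40.9 ± 23.9), and AT2G43870 was 8.77-fold lower, with a log2 change of -3.13 ± 0.36 (SE). UGT78D1, which adds rhamnose to flavonols, went from 134.1 ± 25.3 to 9.77 ± 6.06, under the pseudocount, and AT4G15700 from 200.1 ± 25.8 to 12.7 ± 12.4. Of 3 flavonoid genes tested as a list, UGT78D1 alone fell and 2 did not pass (camera adjusted p = 0.721). Among members of the fixed lists, AT5G51440, a mitochondrial small heat shock protein (HSP23.5), rose 8.47-fold to 1460 ± 197. AT3G13610, the F6'H1 enzyme of coumarin synthesis, rose 5.86-fold to 404 ± 55.6. AT4G17260, lactate dehydrogenase, rose 5.03-fold to 953 ± 28.6, and LTI30, a dehydrin, rose 3.34-fold to 5657 ± 397. Of 20 expansin and XTH genes tested, 4 rose and 2 fell, or 4 and 3 adjusted over the list alone. They included the xyloglucan endotransglucosylase XTH18 (log2 change 2.06 ± 0.31) and the expansin EXPA15 (-1.56 ± 0.30), while the fall of EXPA4 had an adjusted p from 2.07e-05 to 0.193 over the alternatives. Markers that other arrays placed in epidermis were lower in columella by a median of -0.54 log2, with 59 of 200 called lower and 10 higher. In epidermis itself they were lower by a median of -0.43. Their median signal in columella arrays at pH 5.7 was 796 to 868, so they were not faint there. All 3 called vacuolar proton pump genes of 6 fell, with the subunit gene VHA-A1 at -0.81 ± 0.18, and the count adjusted over the list alone was also 3. VHA-A2 (-0.66 ± 0.18) lost its call without pH 4.6 replicate 1, and its adjusted p ranged from 0.00409 to that array's 0.0612 over the alternatives. Of the proton tolerance list, AT1G51340, a citrate efflux transporter of the MATE family, rose from 106.4 ± 3.00 to 246.6 ± 6.49, but its adjusted p of 0.0349 ranged from 2.52e-05 to 0.373 over the alternatives. It lost its call with a pseudocount of 1 and on leaving out any of the 6 columella arrays (0.0738 to 0.0859). In limma, 3496 probe sets passed the threshold, 1695 higher and 1801 lower. The majority turned among the 1499 that changed at least 2-fold, with 797 higher and 702 lower, and in a fit to the 6 columella arrays alone, with 2338 higher and 2329 lower. The 3 and 3 values of 6998 probe sets (41.1%) did not overlap, where chance gives 10%. No list passed camera in columella, where the smallest adjusted p was 0.0998, for the vacuolar proton pumps.

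In the epidermis and lateral root cap, which face the medium, AT5G09570 and PDC2 had the largest rises among the named genes. AT5G09570, a mitochondrial twin-cysteine protein, rose 8.68-fold from 52.5 ± 32.8 to 517 ± 135 (n = 3), and PDC2, a pyruvate decarboxylase, rose 6.48-fold from 47.7 ± 27.4 to 340 ± 44.1. The cysteine protease CP1 rose 5.78-fold to 1570 ± 179, and ICL, isocitrate lyase of the glyoxylate cycle, rose 4.44-fold to 559 ± 68.3. The defensin-like gene AT4G22212 fell by 3.58 on the log2 scale, from 924 ± 587 to 52.7 ± 16.5, and the endoglucanase gene GH9B17 went from 139.9 ± 79.1 to 2.94 ± 1.93, under the pseudocount. AT3G18450 was 8.83-fold lower and AT4G22640 was 7.10-fold lower, with log2 changes of -3.14 ± 0.35 and -2.83 ± 0.41 (SE), and TET12, a tetraspanin, was 5.60-fold lower. Of the 20 expansin and XTH genes, 3 fell and none rose, or 5 and 1 adjusted over the list alone. The root hair genes EXPA18 (2179 ± 1234 to 389 ± 91.7) and EXPA7 (3468 ± 1830 to 925 ± 173) were both lower. Over the alternatives the adjusted p ranged from 0.000109 to 0.0859 for EXPA18, from 0.000479 to 0.103 for EXPA7 and from 0.00353 to 0.111 for XTH33, the third that fell. Both lost their calls with a pseudocount of 1 and without pH 5.7 replicate 1 (0.0722 and 0.103), and EXPA7 also without pH 4.6 replicate 2 (0.0731) and pH 5.7 replicate 3 (0.0511). The dehydrin LTI30 rose 2.28-fold to 5207 ± 745. The 3 cortex markers moved down as a list (camera adjusted p = 0.0472, 2 members lower over all probe sets and over the list alone), with an adjusted p from 0.0383 to 0.318 over the alternatives, the highest with an estimated correlation, and its fallen members AT1G62510 and AT3G21670 reached 0.165 and 0.103. The mean signal of AT3G21670 in epidermis was 25.3 ± 17.3 (n = 6), near the pseudocount. Markers that other arrays placed in columella and in stele were also lower here, with median log2 changes of -0.42 and -0.41 over 200 probe sets each. In columella and in stele themselves these sets were lower by medians of -0.59 and -0.60, so the fall was not particular to the epidermis arrays. In limma, 1731 probe sets passed, 1175 higher and 556 lower, 844 of them at least 2-fold, and 3978 (23.3%) had values that did not overlap, where chance gives 10%. With array medians set equal the excess of rises was gone, with 777 higher and 767 lower. The count rested on single arrays: it was 781 without pH 4.6 replicate 2, 951 without pH 5.7 replicate 1, 785 without pH 5.7 replicate 3 and 2658 (1739 higher and 919 lower) without pH 5.7 replicate 2, an array looked at after seeing the data.

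In cortex, AT5G09570, AT2G21640 and PDC2 were among the largest rises. AT5G09570 rose 15.3-fold, from 104 ± 41.3 to 1693 ± 294 (n = 3), AT2G21640 rose 8.54-fold to 1367 ± 313, and PDC2 rose 8.20-fold from 207 ± 53.7 to 1774 ± 428. AT1G05340 rose 9.05-fold and AT2G32190 rose 8.21-fold, with log2 changes of 3.18 ± 0.27 and 3.04 ± 0.34 (SE). XTH18 rose 4.12-fold to 1927 ± 295, and UGT78D2, a flavonoid glucosyltransferase, rose 2.06-fold to 2903 ± 1261, with an adjusted p from 0.000112 to 0.0672 over the alternatives and the call lost without pH 4.6 replicate 1. The 8 named fallen genes all had their highest mean signal in endodermis. Among them AT4G02090 was 11.5-fold lower (2662 ± 1438 to 194 ± 19.1), AT5G51680 was 9.81-fold lower, the receptor-like cytoplasmic kinase gene AT5G65530 was 9.54-fold lower (3100 ± 1590 to 294 ± 111), and the dirigent gene AT2G39430 was 9.13-fold lower (2769 ± 1284 to 289 ± 139). GSO1 fell 3.65-fold, from 1831 ± 942 to 461 ± 160. AT1G09750, which marks the sorted cells, also fell, from 4102 ± 782 to 1435 ± 337 (log2 change -1.52 ± 0.37, adjusted p = 0.00368), and its adjusted p ranged from 4.65e-06 to 0.0922 over the alternatives, past 0.05 with a pseudocount of 1. Markers that the other arrays placed in endodermis were lower at low pH by a median of -0.98 log2 over 200 probe sets, 106 of them called lower. Of 1280 fallen probe sets, 338 (26.4%) were at least 4-fold brighter in another cell type, against 13.8% of all tested and 8.02% of the risen. Control ratios of 3 prime to 5 prime signal were lower at pH 4.6 by -0.64 and -0.59 log2 for the ubiquitin pairs, -0.58 for an actin pair and, without a pseudocount, -1.01 for a GAPDH pair, each with an exact permutation p of 0.1, the smallest possible. In limma, 3250 probe sets passed, 1970 higher and 1280 lower, 1556 of them at least 2-fold. The 3 and 3 values of 6299 (37.0%) did not overlap, where chance gives 10%. Without the genes brighter elsewhere, 1812 were higher and 942 lower, and without pH 5.7 replicate 3, looked at after seeing the data, 3176 passed. With array medians set equal the majority turned, with 1557 higher and 1670 lower. No list passed camera in cortex. Of 20 expansin and XTH genes, 3 rose and 1 fell, or 3 and 2 adjusted over the list alone, and EXLA1 was 3.01-fold lower (log2 change -1.59 ± 0.31). Of the rises, EXPA8 and XTH19 lost their calls with equal array medians (0.0541 and 0.0963) and on leaving out single cortex arrays (up to 0.143 and 0.152), and EXPA8 also with a pseudocount of 1 (0.0796).

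In the endodermis and quiescent center, AT5G09570 rose 10.7-fold to 3020 ± 761 (n = 3), the highest level it had in any cell type. AT2G21640 rose 9.61-fold to 2031 ± 536, PDC2 rose 8.46-fold to 1375 ± 367, and AT2G41730 rose 7.34-fold to 2804 ± 593. GH3.3, an enzyme that conjugates auxin to amino acids, rose 5.05-fold from 75.1 ± 12.7 to 459 ± 200, and AT3G13610 rose 2.59-fold to 485 ± 116. SWEET17, a vacuolar fructose transporter, was 7.15-fold lower (507 ± 74.2 to 60.9 ± 12.6). The endoglucanase gene GH9B13 was 6.71-fold lower (1202 ± 366 to 165 ± 33.7), AT3G53980 was 8.06-fold lower and AT4G22212 was 8.03-fold lower. AT3G53980, AT4G22212 and 4 others named for their falls (AT5G05250, AT3G45700, AT1G48750 and AT3G59370) had their highest mean signal in stele. XTH21 and EXLB1, also highest in stele, had log2 changes of -1.70 ± 0.38 and -1.68 ± 0.38 (SE). Their adjusted p ranged over the alternatives from 8.74e-06 to 0.0915 and from 0.000203 to 0.0577, and both lost their calls with a pseudocount of 1. Of 20 expansin and XTH genes 3 fell, or 3 adjusted over the list alone, and the third, EXPB1, had an adjusted p from 0.0134 to 0.171. Of 4 tested hypoxia and fermentation genes, PDC2 and AT4G17260 rose, both also when adjusted over the list alone, and the list moved up (camera adjusted p = 0.0472; adjusted p = 0.314 with an estimated correlation). Markers that other arrays placed in stele were lower by a median of -1.07 log2, and 110 of 200 were called lower. In stele itself their median change was 0.27, so they did not fall there as a set. The cause of their fall in the endodermis arrays was not tested. In limma, 2822 probe sets passed, 1635 higher and 1187 lower, 1249 of them at least 2-fold, and 5231 (30.7%) had values that did not overlap, where chance gives 10%. Without pH 4.6 replicate 1 the count was 1582.

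In stele, AT5G09570 rose 14.5-fold from 86.9 ± 38.6 to 1404 ± 416 (n = 3), AT2G21640 rose 8.79-fold to 1001 ± 137, and PDC2 rose 5.23-fold to 642 ± 53.8. AT1G26380, a berberine bridge enzyme-like gene, rose from 9.31 ± 5.17, under the pseudocount, to 145 ± 16.8, and NDB3, an external mitochondrial NAD(P)H dehydrogenase, rose 4.83-fold to 365 ± 85.2. The named fallen genes had their highest mean signal in epidermis or columella. AT3G49190 was 14.9-fold lower (1331 ± 547 to 95.3 ± 93.5), AT3G06460 was 14.1-fold lower (1455 ± 561 to 93.0 ± 43.2), and the jacalin lectin gene AT1G52050 was 12.1-fold lower (979 ± 285 to 76.7 ± 51.1). Markers that other arrays placed in epidermis were lower in stele by a median of -0.89 log2, with 70 of 200 called lower, and were lower in epidermis itself by -0.82. Of 488 fallen probe sets, 100 (20.5%) were at least 4-fold brighter in another cell type, against 6.3% of all tested. The hypoxia and fermentation list moved up (2 of 4 members higher, also over the list alone; camera adjusted p = 0.0472; adjusted p = 0.314 with an estimated correlation), but AT4G17260 lost its call with equal array medians (0.0592) and without any of 4 stele arrays (0.0738 to 0.139). The 3 cortex markers moved down (2 lower, also over the list alone; adjusted p = 0.0193; adjusted p = 0.314 with an estimated correlation), with AT1G62510 at an adjusted p of up to 0.067 over the alternatives. AT3G21670, also on this list, had a mean signal of 22.1 ± 21.7 (n = 6) in stele, near the pseudocount. The 20 expansin and XTH genes moved down as well (2 lower, or 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.0472; adjusted p = 0.318 with an estimated correlation). Its fallen members were EXPA7 (log2 change -1.60 ± 0.46) and EXPA9 (-0.97 ± 0.29), with adjusted p from 0.00247 to 0.207 and from 0.00426 to 0.241 over the alternatives. Both lost their calls with a pseudocount of 1, without any of the pH 4.6 replicates and without pH 5.7 replicate 3, and EXPA9 also without pH 5.7 replicate 2 (0.166). In limma, 1201 probe sets passed, 713 higher and 488 lower, 544 of them at least 2-fold, and 4374 (25.7%) had values that did not overlap, where chance gives 10%. The count was 389 without pH 4.6 replicate 2, 704 without pH 4.6 replicate 3, 686 without pH 5.7 replicate 2 and 480 (315 higher and 165 lower) without pH 5.7 replicate 3, an array looked at after seeing the data. With array medians set equal the majority turned, with 431 higher and 644 lower.

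**Figure D1:**
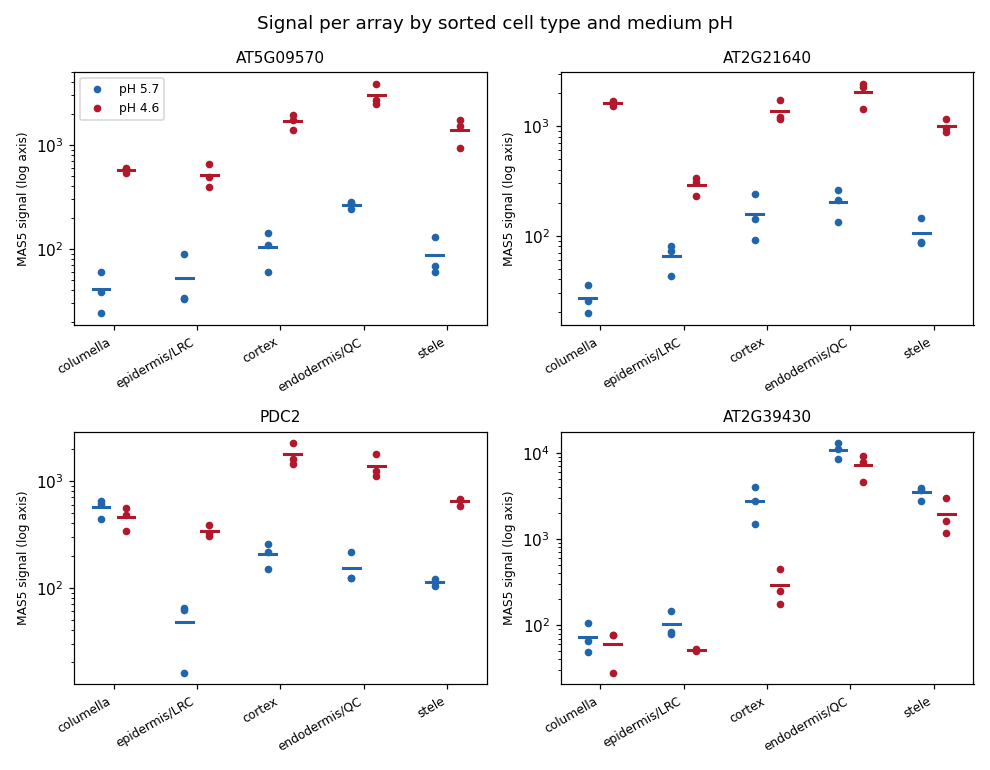
Signal of AT5G09570, AT2G21640, PDC2 and AT2G39430 on each array (points, log axis) by sorted cell type (LRC, lateral root cap; QC, quiescent center), with bars at the mean of 3 arrays, at pH 5.7 in blue and pH 4.6 in red. AT5G09570 and AT2G21640 are higher at pH 4.6 in all 5 cell types, PDC2 is higher in the 4 cell types other than columella, and AT2G39430 is 9.13-fold lower in cortex, where it is dimmer than in endodermis.

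Across the 5 cell types together, AT5G09570 had the largest mean rise among the named genes. The mean log2 rise was 3.57 ± 0.14 (SE, 15 arrays per pH) for AT5G09570, 3.38 ± 0.13 for AT2G21640, 3.11 ± 0.11 for AT2G41730, 2.79 ± 0.17 for AT4G33666 and 2.17 ± 0.13 for ICL. AT2G04050, a transporter of the MATE family, rose by 2.03 ± 0.16, and AT1G26380 by 2.12 ± 0.26. Among the largest mean falls were -2.22 ± 0.18 for the defensin-like gene AT4G22212, -1.85 ± 0.16 for AT2G43870, -1.68 ± 0.20 for GAT1_2.1 and -1.63 ± 0.16 for AT1G52050. Of the fixed lists, hypoxia and fermentation moved up, with 3 of 4 members higher (also over the list alone): PDC2 at 2.18 ± 0.13, AT4G17260 at 0.96 ± 0.09 and AT3G10020 at 0.82 ± 0.26 (camera adjusted p = 0.0472; adjusted p = 0.314 with an estimated correlation). All 3 cortex markers fell (also over the list alone), led by AT1G62510 at -0.97 ± 0.14 and AT3G21670 at -0.80 ± 0.12 (camera adjusted p = 0.0472; adjusted p = 0.318 with an estimated correlation). Outside cortex AT3G21670 had mean signals of 4.56 (columella) to 25.3 (epidermis), under or near the pseudocount. AT1G62510 was at 9.44 in columella and at 91.7 to 177 in epidermis, endodermis and stele. Of 6 vacuolar proton pump genes 4 fell (4 over the list alone), with AT4G02620, a V-ATPase subunit F gene, at -0.53 ± 0.06. The call of AT3G58730 was lost with quantile normalization (0.161) and without any of 15 arrays (0.0517 to 0.0778), and the list itself missed the threshold (adjusted p = 0.0714). Of 20 expansin and XTH genes 8 fell and 3 rose, or 9 and 3 adjusted over the list alone, and the list missed it too (adjusted p = 0.181). EXPA18 and EXPA7 were at -1.03 ± 0.25 and -0.90 ± 0.21, and XTH18 was at 0.97 ± 0.14. The iron deficiency list had 2 of 3 members higher, AT3G13610 (0.99 ± 0.15) and BGLU42 (0.30 ± 0.07), with 2 over the list alone and a list adjusted p of 0.447. Fry tests members without comparing them with other genes, and its p was not adjusted over lists. Its p was 1.51e-05 for the vacuolar pumps, 0.00235 for the expansins and XTHs and 6.52e-07 for iron deficiency. Over the 7 lists named next it ranged from 0.00044 (endodermis markers) to 0.466 (wound and touch). In the other lists tested, the auxin list had 1 of 7 members higher (GH3.3) and 1 lower (WES1), the sulfate list had 1 of 4 higher (SIR), the flavonoid list had 1 of 3 higher (UGT78D2) and the heat shock list had 1 of 5 higher (AT5G51440). The cell cycle list had 1 of 3 lower (AUR2) and the endodermis marker list had 1 of 3 lower (GSO1), and those counts were the same over the list alone. The wound and touch list had 1 of 4 lower (AT1G76640, adjusted p from 0.0097 to 0.095 over the alternatives), or 0 adjusted over the list alone, and all 7 of these lists had camera adjusted p-values of 0.287 or more. The median and mean of a list differed in sign in columella for flavonoid (0.41 and -0.64), iron deficiency (-0.31 and 0.60) and endodermis marker genes, in epidermis for endodermis markers, and in cortex for cell cycle and sulfate genes. For the auxin list in stele, median and mean were above 0 and the test pointed down. In limma, 7165 probe sets passed, 3948 higher and 3217 lower, and 588 changed at least 2-fold on average, 428 of them higher and 160 lower. The majority turned under other scalings, with 3537 higher and 3618 lower after quantile normalization and 3210 higher and 4186 lower with array medians set equal. The latter scaling moved the median of all probe sets by -0.12 log2 in epidermis and by -0.11 in stele.

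The responses of the cell types were then compared with each other. Low pH changes of cortex and endodermis correlated across probe sets with r = 0.662 (Spearman 0.613), those of columella with the other 4 cell types with r from 0.316 to 0.388, and the remaining pairs with r from 0.500 to 0.529. In 100 draws of permuted pH labels per pair, at most 4 gave an r as large in size, and draws can match the real labels. Cortex and endodermis shared 1101 risen and 533 fallen probe sets, where independent lists would share 189 and 89.2. Of 338 fallen cortex probe sets at least 4-fold brighter in another cell type, 185 were brightest in endodermis. Endodermis RNA in the cortex sort, taken up below, could raise the r and the shared calls of this pair. How much of them it accounts for was not tested. Calls of columella and cortex in both went in opposite directions for 91 of 1149 probe sets, against 8 of 1642 for cortex and endodermis. Probe sets called higher in all 5 cell types numbered 202, with 96 single genes, and those called lower in all 5 numbered 17, with 8 single genes. The latter were AT2G43870, AT5G23840, AT1G52910, the glutathione transferase GSTU26, AT5G23830, AT2G43535, the carboxypeptidase-like gene SCPL34 and AT3G25290, named after their values were seen. As each cell type came from its own marker line, differences between cell types cannot be told apart from differences between lines. The interaction test passed for 2132 probe sets. Its 10 genes with the smallest p included AT2G41730, which rose in every cell type but by log2 changes of 6.71 in columella and 1.15 in epidermis. AT5G42830 and AT3G54520 changed by 5.12 and 5.21 in columella and by at most 0.35 and 0.54 elsewhere. The clock gene GI was lower in columella, at -2.56, and higher in cortex, at 1.09. AT1G24095 changed by 2.65 in cortex, 2.07 in endodermis and 1.60 in stele, and by -0.49 in columella. PDC2, higher in the other 4 cell types, was not among these 10 but also differed between cell types (interaction adjusted p = 3.34e-06).

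**Figure D2:**
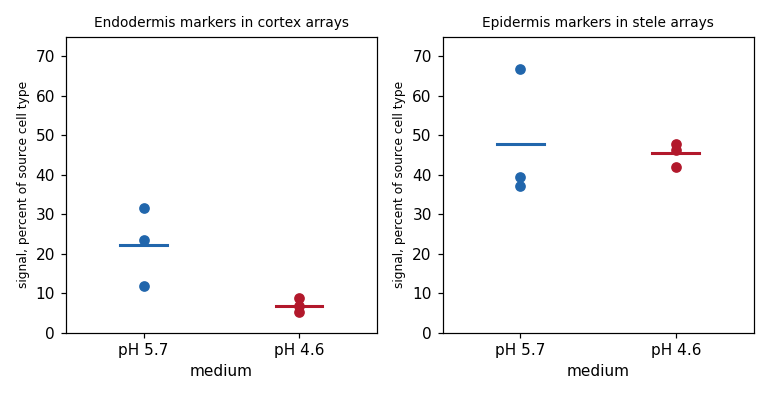
Median signal of abundant endodermis markers in each cortex array (left) and of abundant epidermis markers in each stele array (right), as a percent of the signal in the source cell type at the same pH (linear axis), with points for arrays and bars at the mean of 3. The endodermis markers lie between 11.8% and 31.5% in cortex at pH 5.7 and between 5.29% and 8.71% at pH 4.6, and the epidermis markers overlap between pH values in stele, from 37.1% to 66.9%.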

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

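The interaction test, the test of array scaling on the risen genes and the counts over other splits of the arrays were planned, and the other tests in this part were chosen after the results were seen.

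Endodermis genes were lower in the cortex arrays at low pH, with a median of -0.98 log2 over 200 markers. A lower share of cortex cells at pH 5.7, made up evenly by all other cell types, would raise their markers alike. The highest other median lay 1.02 log2 above that of the endodermis markers, which argues against that even case. A lower share made up mainly by endodermis cells would give the same gap, so it stays open. The other scalings moved the median of the endodermis markers away from 0, to -0.99 and -1.08. RNA of endodermis cells in the cortex sort, despite the GFP gate, is a candidate explanation: 2.11% of 95 abundant endodermis markers lay below 50% of the level that the needed share of 14.3% gives at pH 5.7, and their signal was 11.8% to 31.5% of that in endodermis at pH 5.7 and 5.29% to 8.71% at pH 4.6. By the same measure 80.4% of such markers fell short in columella, 83.9% in epidermis and 0% in stele, so the level alone does not single out cortex. The markers were chosen without the cortex arrays, so genes that cortex cells express themselves could also meet the level. The lower share at pH 4.6 restates that the markers fell more in cortex (-0.98) than in endodermis (-0.51), and so is no separate support. A fall in every cell type that expresses these genes was left open by endodermis (ratio of median changes 0.522, 0.272 to 0.655 on leaving out single arrays), and a test in stele, added after that was seen, argues against it: the 86 markers at least as bright there as in cortex changed by a median of -0.18, a ratio of 0.128 to their cortex change (0.00981 to 0.196 with the fallen probe sets and on leaving out single arrays); a fall in cortex cells themselves was not tested and stays open.

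Epidermis genes were lower in the stele arrays at low pH, with a median of -0.89 log2 over 200 markers. A lower share of stele cells at pH 5.7, made up evenly by the other cell types, is argued against by the highest other marker median, 1.14 log2 above. A lower share made up mainly by epidermis cells would give the same gap, so it stays open. Scaling is argued against by a median of -1.01, and a single array by -0.639 without pH 5.7 replicate 3. RNA of epidermis cells in the stele sort, despite the GFP gate, may contribute, since 1.25% of 80 abundant epidermis markers fell short of the needed level. But 16.9% fell short in columella too, which also meets the bar of 25% set for the level. Shares overlapped between pH values (37.1% to 66.9% at pH 5.7, 42.0% to 47.8% at pH 4.6). From group means the median share was higher at low pH (50.1% against 46.7%). The mean of the shares per array was lower at low pH, with 46.4%, 42.0% and 47.8% against 37.1%, 39.4% and 66.9%. The direction thus hangs on the averaging and on pH 5.7 replicate 3, and epidermis RNA as the source stays open. A fall of these genes in both cell types cannot be told apart from it, as the ratio of the changes was 0.915 for the markers and 0.472 for the fallen probe sets.

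The 12 genes named for the mean rise were higher at low pH in all 5 cell types, as the naming rule requires. The smallest of their mean changes was 1.92 log2 under the other scalings, which argues against scaling as the cause. RNA quality was not excluded, since the 3 prime to 5 prime ratio of 1 GAPDH control pair was lower at pH 4.6 (-0.49 log2, permutation p = 0.00017, 15 arrays per pH) and so differed between the same groups that the comparison sets apart. Both probe sets of that pair were higher at low pH, by 0.472 log2 (3 prime) and 0.964 (5 prime), so its ratio may not measure quality alone. The other GAPDH pair was at -0.09 log2 (permutation p = 0.292), and the actin and ubiquitin pairs had permutation p from 0.284 to 0.724. These p-values pool the cell types, while in cortex alone several ratios were lower at pH 4.6, as given above.

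For each single cell type the 6 arrays make 10 splits, too few for a share under 0.05. In columella 1 of 10 splits gave as many probe sets (3496, highest other 2), in epidermis 1 (1731, highest other 60), in cortex 1 (3250, highest other 2), in endodermis 1 (2822, highest other 42) and in stele 1 (1201, highest other 0). The real labels count as 1 of the splits here. For the mean response 1 of 100 splits, the real one, gave as many (7165, highest other 2133). For the interaction 2 of 100 did (2132, highest other 3881). Both shares lay under 0.05 for these arrays. The splits break up any pH effect, so they do not test a difference between cell types alone. If the replicates are technical, the splits cannot exclude chance between cultures or sorting days. The highest other split in both parted 3 cell types exactly by pH, in the interaction with 2 of them turned round, and so holds the pH effect; among 61 splits that parted no cell type by pH the highest count was 1.

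The low pH change differed between cell types, each from its own marker line, by the interaction test for 10 genes chosen by smallest p. Cell type and line cannot be told apart here. The gap between the highest and lowest change was 5.56 log2 for AT2G41730 (interaction adjusted p = 6.36e-11), 5.44 for AT5G42830 (3.28e-09), 5.27 for AT3G54520 (5.81e-08) and 4.46 for AT1G05060 (1.61e-08), each highest in columella. It was 3.65 for the clock gene GI (9.17e-08), lowest in columella, and 3.14 for AT1G24095 (5.23e-09), highest in cortex. For AT5G15950, ASPGB1, AT5G65660 and AT5G56350, each highest in columella, it was 3.39 (1.08e-07), 3.08 (2.6e-07), 2.34 (6.51e-08) and 2.27 (2.34e-07).

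Control probe sets outside the comparisons also carried signal. A control probe set had a mean signal of 14810 in the 6 columella arrays (13700 to 15620) and 8.10 in the 24 others (0.777 to 19.4). All 5 GAPDH controls were higher at low pH in all 5 cell types, by 0.472, 0.964, 0.918, 0.865 and 0.951 log2 (permutation p = 1e-05 each, the smallest possible), and by 0.403 to 0.895 with array medians set equal.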

How the results depend on the processing

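The counts without probe sets brighter in another cell type were chosen after seeing the data, and the other alternatives were planned. No named gene and no list that passed changed direction under any alternative run on it, while the majority direction of the counts in cortex, stele and the mean response turned with equal array medians, that of the mean response also with quantile normalization, and that of columella with the 2-fold limit and with its 6 arrays alone. Of 185 named gene results, 33 lost their call under at least 1 alternative.

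Requiring a 2-fold change left 1499 probe sets in columella, 844 in epidermis, 1556 in cortex, 1249 in endodermis, 544 in stele and 588 in the mean response, as a stricter limit must. Array weights gave 3331 in epidermis, 5751 in cortex and 4971 in the interaction, and the cause was not tested. Fits to the 6 arrays of a cell type gave 460 in epidermis, 1268 in endodermis and 631 in stele, but 4667 in columella and 3187 in cortex, and the cause was not tested. Of 7 list calls, 0 passed with a pseudocount of 1, 3 with the median of each array set equal, 2 with a replicate block and 0 with an estimated correlation, and the cause was not tested.

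Leaving out 1 array at a time gave 2671 to 3758 probe sets in columella, 781 to 2658 in epidermis, 2215 to 3558 in cortex, 1582 to 3105 in endodermis, 389 to 1452 in stele, 6784 to 7392 in the mean response and 1667 to 2742 in the interaction. List calls ranged from 1 to 9. They were 1 without epidermis pH 4.6 replicate 2, cortex pH 5.7 replicates 1 and 3, endodermis pH 4.6 replicates 2 and 3, endodermis pH 5.7 replicates 1 and 3, stele pH 4.6 replicates 2 and 3 or stele pH 5.7 replicate 1, and 2 without stele pH 5.7 replicate 3. Markers highest in the cell type of their list numbered 6 to 7 of 10. Deviations from the group mean correlated across probe sets with r over 0.1 for 6 of 15 pairs of arrays of a cell type that share a replicate number (-0.135 to 0.211). These include all 3 pairs in epidermis (0.176, 0.181 and 0.121), so pairing by number is not excluded there. With a replicate block 2 of the 7 list calls held, those of the expansin and XTH list and the cortex markers in stele. The cortex marker list in epidermis then had a camera adjusted p of 0.0667 (0.0383 to 0.318 over the alternatives). The number of arrays limits precision, and a change of pseudocount acts most on signals near background.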

Other observations

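All tests in this part were chosen after the results were seen. Several gene families were lower at low pH. In epidermis 5 of 11 GH9 endoglucanase genes fell and 0 rose (median log2 change -0.88, camera adjusted p = 0.000115; adjusted p = 0.00793 with an estimated correlation), and in the mean response 8 of 11 fell (median -0.68, adjusted p = 0.00108; 0.0246 with an estimated correlation). Trichome birefringence-like (TBL) genes, which act in wall polysaccharide acetylation, fell for 7 of 18 members in cortex (median -0.50, adjusted p = 0.000579; 0.103 with an estimated correlation) and 6 of 18 in endodermis (median -0.57, adjusted p = 0.00108; 0.14 with an estimated correlation). Serine carboxypeptidase-like (SCPL) genes fell for 8 of 20 in columella (median -0.65, adjusted p = 0.00108; 0.0624 with an estimated correlation). Beta-tubulin (TUB) genes fell for 3 of 5 in cortex (median -0.53, adjusted p = 0.0398; 0.43 with an estimated correlation), and tetraspanin (TET) genes for 3 of 12 in endodermis (median -0.52, adjusted p = 0.0389; 0.374 with an estimated correlation). Of 204 family tests 20 passed, and 2 passed with an estimated correlation, both for GH9. The medians of the 20 were below 0 under each scaling. In the same arrays markers that the other arrays placed in another cell type fell: endodermis markers in cortex (median -0.98, 106 of 200 called lower) and stele markers in endodermis (median -1.07, 110 of 200 called lower). In columella epidermis markers fell (median -0.54, 59 of 200 called lower), and in epidermis stele markers (median -0.41, 53 called lower) and columella markers did (median -0.42, 37 called lower). All of these sets were chosen without the arrays they were read in, so the sorted cells may express them too. At pH 5.7 the epidermis set had median signals of 796 to 868 in columella arrays, and the stele set 292 to 623 in epidermis arrays. In their own cell types the epidermis, stele and columella sets also fell, by medians of -0.43, -0.60 and -0.59. Which cells the fallen family members came from was not tested.

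The 69 tested plastid-encoded probe sets had medians of -0.35 in epidermis, -0.44 in endodermis and -0.45 in stele, and of 0.29 in cortex and -0.01 in columella, with 0 members called in any cell type (camera adjusted p = 0.00425, 0.0119 and 0.000377; 0.788, 0.794 and 0.709 with an estimated correlation for the first 3). In cortex and columella the adjusted p was 0.34 and 0.959.

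A mitochondrial stress response at low pH was examined with 10 tested genes known from such stress. The 3 that the naming rule had not named were NDB4 (mean log2 change 1.75), AT2G04070 (0.71) and NDB2 (0.34), with a median of 0.712. The rise may be part of such a response, but fewer than 3 of the listed genes had not been seen before the test, which leaves it open.

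NRPA2, NRPC2 and NRPA1, genes of RNA polymerases I and III, were among those called higher in all 5 cell types. NRPC1 was higher in all 5 but was not called in each. NRPA2, NRPC2, NRPA1 and NRPC1 had mean log2 changes of 1.76, 1.70, 1.52 and 0.66, and their median of 1.61 lay 1.17 above that of 8 NRPB, NRPD and NRPE genes (0.43). Low pH may raise these subunits as a group, but fewer than 3 members were unseen before the test, which keeps this open.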
